A study of Drosophila melanogaster with 2 samples.

How the data were processed

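Chromatin was precipitated with an antibody against GFP from whole embryos of a line with eGFP at the C terminus of Med, sheared by sonication to fragments of 200 to 800 bp, and sequenced, per the labels. The 2 libraries are biological replicates 2 and 3 of 1 group and come from separate biosamples, per the labels. In each of the builds dm6 and dm3 the authors deposited 4 lists: a relaxed peak list per replicate, a relaxed list called on both replicates together, and an optimal list thresholded by the irreproducible discovery rate. Per the deposited manifests, both replicates were called against the same control file in each build, so the replicates share any error of that control. Aligner, peak caller, versions and the threshold of the optimal list are not given in the sources used here.

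The deposited signal value of each peak is the authors' own, on a scale that is not given in the sources used here, and it was used to rank and describe peaks within a list. Ratios of signal between the replicate lists are given as log2 values or relative to their median over all matched peaks, because the lists can differ in scale. The deposited −log10 q value reached a ceiling, which 76.0% of the reproducible dm6 peaks shared at 3.95, so it was not used to rank. Relaxed lists ended at 30000 peaks, and 92.0% and 91.4% of the replicate peaks had 1 common width per list, 380 bp and 370 bp. Read totals were not used here, so the depth of the libraries is unknown, and Wilson intervals on shares of peaks cover counting error only. No position and signal were identical between the replicate lists.

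Genes and TSSs came from the Ensembl annotation of BDGP6.54, release 115, and sequence from the Release 6 assembly, both on dm6 coordinates of the 6 main arms. Positions were converted to count from 1. A summit was a promoter summit within 1000 bp of a TSS of any of 13945 protein-coding genes, of which 4360 had one, and otherwise was assigned in the order 5′ UTR, 3′ UTR, coding exon, intron, non-coding gene and intergenic. Replicates were compared over as many of their strongest peaks as the reproducible list held, with summits within 100 bp counted as shared, and against 100 seeded circular shifts along each arm. Replicate signal at a reproducible peak was that of the strongest overlapping relaxed peak.

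For each of 22 gene lists the share of occupied members was tested against other protein-coding genes (all annotated genes for tRNA genes) by a two-sided exact conditional test within 4 strata of TSS number (1, 2, 3 to 4, and 5 or more), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Where summits in the gene body were counted, the strata were also split by gene length. Genes are not independent replicates, and neighbours can share a summit, so these p values describe this peak list only. The list members and motifs were fixed before the data were examined. Of the members 8 symbols were not found in the annotation and counted as not measured. For 21 motifs, 101 bp windows at summits were compared with windows 500 bp to either side by a two-sided exact sign test against 1 flank drawn at random with a fixed seed, adjusted over the motifs, and the printed flank share is the mean of both flanks. Genes were named by a rule fixed before the data were examined: Med, the genes nearest to the 12 strongest peaks, every Dpp target, and in each other list the 4 occupied members with the strongest promoter peak, with neighbours that share a summit. In lists that were mostly unoccupied, up to 4 members without a promoter summit were named in alphabetical order. The genes dpp and wit, the intronic summits of Hox genes and the peaks at Mnat9, emc, l(2)k01209 and InR were picked out after their values were seen.

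Alternatives fixed in advance were a stricter list, each replicate alone, other distances, windows, backgrounds and strata, and dm3. The list of strongest pooled peaks, also planned, was identical to the reproducible list and changed nothing. Alternatives chosen after seeing the data were reproducible peaks with a summit of the top lists of both replicates within 100 bp, members matched through renamed symbols (6 of 8), a tRNA background without transposable elements, and other draws of the flank. The tests were tested on simulated data. For gene list occupancy over 13945 genes, lists of 20 genes at 2 times the base occupancy passed an unadjusted threshold in 64.5% of 200 runs and lists of 90 genes in 100% of them, against 5% and 3.5% of runs with no difference. The genes of these runs were independent, unlike neighbours that share a summit. For motif occurrence over 5867 peaks, 100 planted sites raised the windows with a site from 13 to 113. Simulated summit and flank windows had the same base composition, unlike the data. For replicate overlap over 5867 peaks, 58.8% was found where 58.6% was planted, at distances below the matching distance. The motif and overlap runs thus checked the counting only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.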

Results

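Binding of Medea was mapped in Drosophila melanogaster embryos by chromatin immunoprecipitation followed by sequencing. Medea, encoded by Med, is the common-mediator Smad of the fly and carries signals of the Dpp (BMP) and activin pathways into the nucleus together with the receptor-activated Smads Mad and Smox. The embryos came from a transgenic line with eGFP fused to the C terminus of Med, were collected between 0 and 24 h as whole animals of both sexes, and were precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, numbered 2 and 3 in the labels, so the design gave a map of occupancy and the agreement of the replicates, not a contrast between conditions. Each relaxed peak list held exactly 30000 peaks. The read depth of the libraries was not known from the peak lists. All positions are in build dm6 unless dm3 is named, and signal is the authors' value per peak. Its scale is not given in the sources used here and can differ between the replicate lists, so a ratio of replicate signals has no fixed zero.

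The list of reproducible peaks held 5867 peaks that covered 1.71 Mb, and its strongest sites lay at promoters of Ugalt, CG14100, Chro and PNPase and inside the genes ush and CG11050. Its peaks had a median width of 359 bp and signals from 164.6 to 8099, with a median of 282.0. The 5867 reproducible peaks were the 5867 strongest of the list called on both replicates together, so a peak could enter with most of its signal from 1 replicate. Of the 5867 strongest peaks of replicate 2, 3915 had a summit within 100 bp of a summit among as many of replicate 3, a share of 66.7% (Wilson 95% interval 65.5 to 67.9). Across 100 circular shifts along the chromosomes the mean share was 0.876% and the highest 1.19%. Of the reproducible summits, 80.9% had a summit of the top list of replicate 2 within 100 bp and 84.97% had such a summit in replicate 3, and 67.4% had both. Signal in the replicates was correlated across 5553 reproducible peaks found in both relaxed lists, with a Spearman rho of 0.66. It is a value over the whole list and need not hold for weak peaks. Among the 1388 peaks with the strongest pooled signal rho was 0.703, and among the 1388 with the weakest it was -0.595. The pooled signal draws on both replicates, so a narrow range of it can by itself push rho below zero. The negative value therefore cannot decide how the replicates rank weak peaks. These are correlations across peaks, which are not independent replicates. The log2 ratio of replicate 3 to replicate 2 signal had a median of 0.33 and an SD of 0.75 over the 5553 peaks.

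Summits lay mostly at promoters, and the stronger peaks did so more often. Of the 5867 reproducible summits, 3657 (62.3%) were within 1000 bp of the start of a protein-coding transcript (TSS), against 20.3% on average and at most 22.3% over 100 circular shifts. The share was 58.0% in the top list of replicate 2 and 64.6% in that of replicate 3. Introns held 24.4% of summits against 36.2% in the shifts, intergenic sequence 10.2% against 26.3%, and coding exons 0.307% against 10.2%. Promoters were assigned first, so their higher share by itself lowers the shares of all other classes. The lower share of introns therefore does not show that introns were avoided. Of the 2210 summits away from promoters, 1431 lay in introns. The shifts ran over whole arms, also over stretches without reproducible peaks, such as 3L beyond 23.3 Mb of 28.1 Mb. Their shares are therefore not those of the peak-bearing sequence alone. The median distance to a TSS was 368 bp, with 528 bp in replicate 2 and 271 bp in replicate 3. With the list ordered by signal and split into 4 equal parts, the promoter share was 67.8% in the strongest part and 63.9%, 60.7% and 57.0% in the following parts. Promoter peaks had a median signal of 295.8 and distal peaks of 262.9 (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest they can give). The difference of 32.9 was 12.98 in the top list of replicate 3 alone and 27.8 in that of replicate 2 alone. Each value is on the scale of its own list, so the direction can be compared between the lists but not the size.

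The X chromosome carried 1118 summits, or 1.21 times the share expected from its protein-coding genes, with 1.34 in replicate 2 and 1.13 in replicate 3. Against the length of the arms in place of their genes the ratio was 1.08, with 1.20 in replicate 2 and 1.01 in replicate 3. Chromosome 4 carried 19 summits, or 0.565 times its expected share, with 0.683 and 0.743 in the replicates. The arms 2L, 2R, 3L and 3R lay between 0.913 and 0.994 times the expected share. No test was made of these shares.

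The strongest peak, on X from 2703663 to 2704110, lay at the promoters of Ugalt, a UDP-galactose transporter gene, and eIF2Bbeta, a subunit gene of a translation initiation factor, with summit 28 bp and 691 bp from their TSSs. Its signal was 8099 in the reproducible list, 3658 in replicate 2 and 4467 in replicate 3. The next, on 3L from 19590410 to 19590838, lay 97 bp from the TSS of CG14100 with a signal of 7969. The peak ranked 3 lay on 2L from 480576 to 481367 in an intron of ush, the gene of a GATA cofactor, with a signal of 6495, and 1405 bp from cbt, whose TSS was the nearest. An intronic peak of CG11050 followed, on 2L from 6612460 to 6612952, with a signal of 5799. Chro, the gene of the chromodomain protein Chromator, and Ssl1, a subunit gene of TFIIH, shared a promoter peak on 3L from 22878681 to 22879133 (signal 5499). PNPase and Gprk2 shared the next, on 3R from 31404459 to 31404852 (signal 5274). The remaining 6 of the 12 strongest peaks lay at ph-p, a Polycomb group gene, on X from 2137120 to 2137598 (signal 4909), at px on 2R from 22514088 to 22514508 (signal 4890), between Tcs5 and CHMP2B on 3L from 5139299 to 5139698 (signal 4460), at Lk6 on 3R from 11760850 to 11761261 (signal 4425), in an intron of CG32772 on X from 4910177 to 4910611 (signal 4371) and at CG9663 on 2L from 3301907 to 3302593 (signal 4345). All 12 were found in the relaxed lists of both replicates, with signals from 1954 to 3895 in replicate 2 and from 2070 to 4467 in replicate 3.

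At Med itself (FBgn0288966, 3R from 31611046 to 31615375, plus strand) a promoter peak from 31610865 to 31611240 had its summit 7 bp from the TSS, with a signal of 292.2 and rank 2805. It overlapped a replicate 3 peak with a signal of 272.8 and no relaxed peak of replicate 2, and CycG had a TSS within 1000 bp of the same summit. Downstream of Med, a peak from 31615999 to 31616396 at Mnat9 ranked 24 with a signal of 3178, and both replicates held it at 1586 and 1593. The gene CG1792, on the plus strand from 31616303, starts inside the same peak. In the 25000 bp around Med the relaxed list of replicate 3 held 26 peaks and that of replicate 2 held 9, against means of 11.5 and 8.24 over windows of that length with a similar number of TSSs. The peaks of replicate 3 from 31600948 to 31608215 lay inside CycG, upstream of Med, where replicate 2 held no peak.

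**Figure D1:**
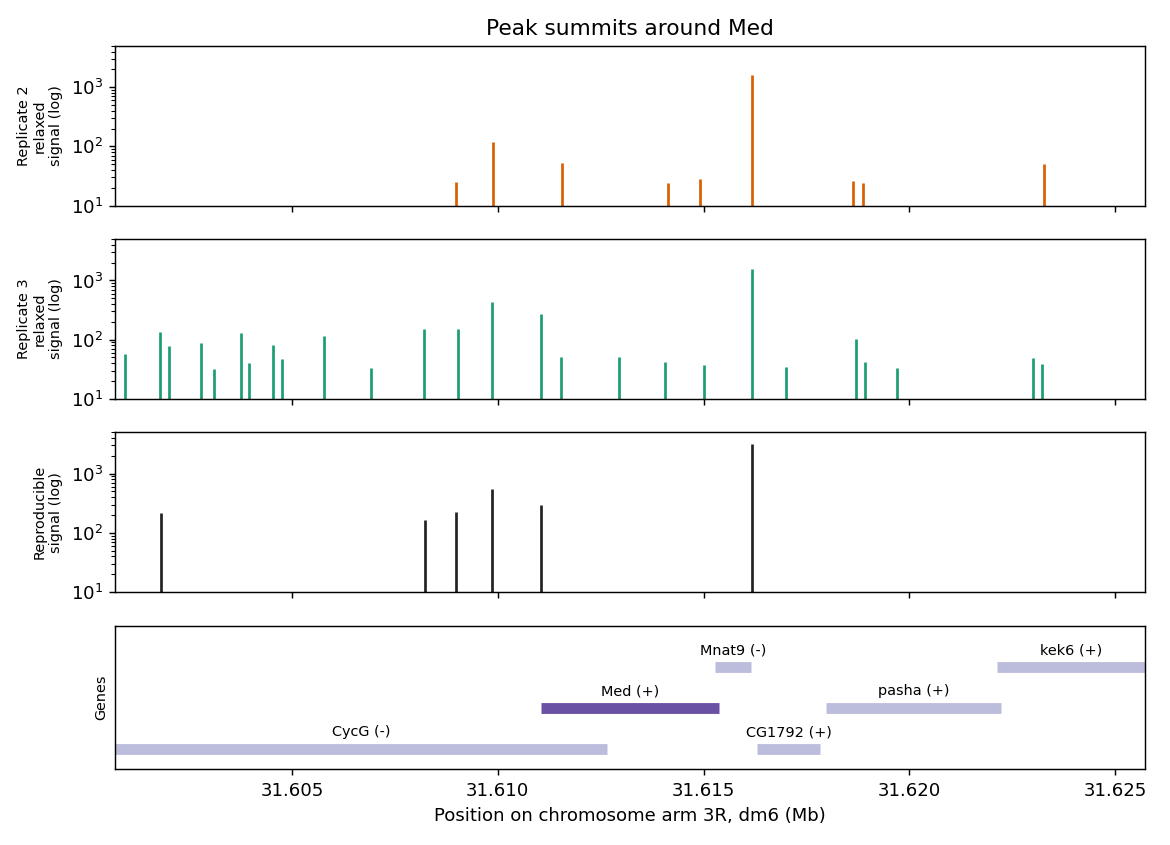
Summits of peaks in the 25000 bp around Med on arm 3R of dm6, with signal per peak on log axes for the relaxed lists of both replicates and the reproducible list, and gene spans with their strand. Replicate 3 holds 26 summits in the window and replicate 2 holds 9, and the peak at Mnat9 and CG1792 stands highest in each of the 3 lists.

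Known targets of Dpp were occupied at their promoters about as often as other genes, and several carried peaks in introns or flanks instead. Of 22 targets 7 had a summit within 1000 bp of a TSS, a share of 31.8% against 34.7% expected from other genes with as many TSSs (ratio 0.918, exact stratified test, Benjamini-Hochberg adjusted p = 1). Those 7 were brk, the repressor of Dpp target genes (X from 7307344 to 7307933, signal 717.8), ush (585.2), the homeobox genes C15 (337.3) and tin (316.6), the BMP-binding protein gene cv-2 (236.1), Ance with Smg5 (187.9) and the zinc finger gene peb (167.1). The promoter peak of brk had 118.0 in replicate 2 and 606.9 in replicate 3, and the promoter peak of cv-2 overlapped no relaxed peak of replicate 2. A further 7 targets had summits only inside the gene or within 1000 bp of its ends. Among them, Dad, the inhibitory Smad gene, had an intronic peak on 3R from 17056233 to 17056627 with a signal of 947.4 and rank 378 (160.0 in replicate 2 and 769.3 in replicate 3), and egr had an intronic peak with a signal of 737.0. Peaks of bi (441.9), Doc1 (439.9), tup (259.9), Doc2 (235.1) and lab (167.9) were weaker. The peak counted for tup lay 21919 bp from the tup TSS, within 1000 bp of a TSS of another gene. No summit was found in or within 1000 bp of zen, Doc3, pnr, Dtg, salm, bap, vg or bam. With summits anywhere in the gene or within 1000 bp counted, 14 of 22 targets were occupied, 63.6% against 49.3% expected (exact test with strata also of gene length, adjusted p = 0.31).

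Components of the BMP and activin pathways were occupied above expectation in the reproducible list, 14 of 24 members or 58.3% against 34.3% (ratio 1.70, exact stratified test, adjusted p = 0.032). The 14 included Med, the tagged gene itself, whose promoter summit CycG shared. The promoter peaks of Med and sax overlapped no relaxed peak of replicate 2. The strongest promoter peaks were at Mad, the receptor-activated Smad of the pathway (signal 938.8), shn, a zinc finger partner of Mad and Med (730.8), srw, whose summit CG11583 shared (407.9), and myo, whose summit ey shared (377.6). The promoter peaks of the ligand gene dpp (184.1, with 33.3 in replicate 2 and 143.2 in replicate 3) and the receptor gene wit (300.2, with 146.5 and 161.8) were picked out after their values were seen. Both genes had a stronger intronic peak. That of dpp had a signal of 669.7 (307.9 in replicate 2 and 355.6 in replicate 3) and that of wit 1371 (616.0 and 760.3). The peak of shn had 29.4 in replicate 2 and 648.3 in replicate 3. The call was lost in the top list of replicate 2 alone (9 of 24, adjusted exact p = 0.72) and of replicate 3 alone (14 of 24, adjusted exact p = 0.062). It was also lost in the stricter list of the 2933 strongest peaks, with promoters of 500 bp or 5000 bp, with summits in the gene body counted, with strata of gene length, and among the 3955 reproducible peaks with summits in the top lists of both replicates, where the ratio was 0.958, and the adjusted p over the alternatives ranged from 0.025 to 1.

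Ribosomal protein genes were the list most often occupied above expectation, with 72 of 92 members or 78.3% against 36.5% (ratio 2.14, exact stratified test, adjusted p = 7.5e-16). The share was 81.5% in replicate 2 and 79.3% in replicate 3, each past the threshold (exact stratified test, adjusted p = 4.97e-20 and 3.25e-16). The strongest were RpS27 with Nup37 (signal 2577), RpL7 with Ripalpha (2279), RpL14 with Nelf-E (1927) and RpL23A (1820). Proteasome genes had 22 of 48 members occupied, 45.8% against 29.7% (adjusted exact p = 0.035), led by Rpn5 with Hat1 (814.3), Rpn6 with ave (663.5), Rpt5 with RanBP3 (533.8) and Rpn3 with l(2)37Bb (523.6). Members without a summit included Prosalpha1, Prosalpha1R, Prosalpha3T and Prosalpha4. The proteasome call was lost in each replicate alone (18 of 48 in both, adjusted exact p = 0.32 in replicate 2 and 0.46 in replicate 3), at 5000 bp, without strata, without list genes in the background and among peaks in both top lists. In the stricter list the ratio was 0.944, and the adjusted p over the alternatives ranged from 0.0073 to 1.

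Cuticle protein, odorant and gustatory receptor, yolk and chorion, muscle structure and neuronal genes were occupied less often than expected. Cuticle protein genes had 1 of 93 members occupied against 26.9% expected (ratio 0.040, adjusted exact p = 9.3e-11), and the occupied member Cpr73D shared its summit with Ogdh. Odorant and gustatory receptor genes had 3 of 120 occupied against 27.0% (ratio 0.092, adjusted exact p = 5.9e-12), and Or88a, Gr63a and Gr32a shared their summits with CG12402, Lamtor4 and Idua. Yolk and chorion genes had none of 17 (27.1% expected, adjusted exact p = 0.028), among them Cp15, Cp16, Cp18 and Cp19. Muscle structure genes had 3 of 22 against 47.3% (adjusted exact p = 0.0045), with sls, the titin-like gene, at 1015, TpnC47D at 213.8 and Tm1 at 194.8, and without Act57B, Act79B, Act87E and Act88F. Neuronal genes had 3 of 22 against 46.7% (adjusted exact p = 0.0051), with the RNA-binding protein gene elav at 1255, Syx1A with CG10694 at 331.8 and Csp with CG11523 at 213.8, and without Appl, ChAT, Gad1 and Rab3. These 5 lists passed the same exact stratified test in both replicates alone. The test counts each gene as independent, also where members of a list are neighbours, so its p values describe this peak list only. The calls of muscle and neuronal genes were lost without strata of TSS number (ratio 0.436 for both), those of neuronal and yolk and chorion genes in the stricter list and among peaks in both top lists, and that of yolk and chorion genes with strata of gene length.

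Hox genes had none of 8 promoters occupied against 44.2% expected (exact stratified test, adjusted p = 0.025), which was past the threshold in both replicates. Abd-B, Antp, Dfd and Scr were among them, and Antp, Ubx, Abd-B and lab carried intronic summits, so that 4 of 8 were occupied over the gene body against 61.5% expected (strata also of gene length, adjusted exact p = 0.63). The promoter call was also lost at 5000 bp, where the ratio was 0.806. It was lost without strata, in the stricter list and among peaks in both top lists too, but there the ratio stayed at 0. Anteroposterior segmentation genes had 4 of 31 against 33.6% (adjusted exact p = 0.028), with fkh at 724.8, bcd at 653.1, cad at 235.0 and wg at 170.6, and without D, Kr, btd and croc. That call was lost in replicate 3 alone (6 of 31, ratio 0.565, adjusted exact p = 0.19), at 500 bp, without strata and in the stricter list, with adjusted p from 0.0059 to 0.20 over the alternatives. The peak of cad overlapped no relaxed peak of replicate 2. That of wg had 26.0 in replicate 2 and 142.9 in replicate 3, fkh 148.3 and 561.4, and bcd 314.0 and 343.9.

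The other signalling lists did not pass the threshold. Wingless pathway genes had 12 of 21 occupied, 57.1% against 34.8% (adjusted exact p = 0.059), led by the kinase gene sgg (signal 1234), wls with Adck5 (310.8), nkd (298.4) and arr (263.5). Notch pathway genes had 11 of 22 against 30.6% (adjusted exact p = 0.10), led by Su(H) with CIAPIN1 (407.0), N (377.5), mam with RN-tre (324.3) and kuz with B4 (320.5). EGFR pathway genes had 9 of 18 against 36.8% (adjusted exact p = 0.43), led by the ligand gene spi (1276), Ras85D with Rlb1 (627.4), aop (581.8) and sty (465.3). Hedgehog pathway genes had 3 of 13 against 30.5% (adjusted exact p = 0.84), smo with CG17078 (336.6), disp with ECSIT (300.9) and ptc (167.9), and without Su(fu), boi, ci and cos. The Hedgehog ratio of 0.758 was 0.264 in replicate 2 alone (1 of 13) and 0.992 in replicate 3 alone (4 of 13). The peak of smo overlapped no relaxed peak of replicate 2. Wingless genes passed with promoters of 500 bp or 5000 bp and Notch genes at 5000 bp and with strata of gene length, but among peaks in both top lists the ratios were 0.540 and 0.988.

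Tissue and patterning lists that did not pass were as follows. Dorsoventral patterning genes had 8 of 23 occupied against 40.2% (adjusted exact p = 0.76), with pyr at 291.0 and rho at 287.4 besides brk and ush, and without Dr, ind, pnr and scw. In replicates 2 and 3, pyr had 31.7 and 253.4 and rho 31.4 and 244.4, while ush had 297.5 and 278.0. Tracheal genes had 4 of 15 against 41.2% (adjusted exact p = 0.41), with bnl at 303.0, trh at 183.2 and pnt at 173.6 besides ush, and without btl, esg, kni and knrl. The peak of pnt had 26.8 in replicate 2 and 154.6 in replicate 3, that of bnl 77.5 and 224.2 and that of trh 82.6 and 87.0. Cardiac and visceral mesoderm genes had 4 of 20 against 37.5% (adjusted exact p = 0.23), with tin, sli at 243.1, Mef2 with Pal1 and Pdrg1 at 218.6 and zfh1 at 168.0, and without Doc1, Doc2, Doc3 and H15. Hemocyte genes had 5 of 18 against 34.8% (adjusted exact p = 0.75), with ush, NimC4 at 355.7, srp at 283.2 and Hml at 272.5, and without Col4a1, He, NimC1 and PPO1. The hemocyte ratio of 0.797 was 0.503 in replicate 2 alone (3 of 18) and 0.626 in replicate 3 alone (4 of 18). The peak of srp had 34.0 in replicate 2 and 239.6 in replicate 3, and that of NimC4 179.6 and 167.9. The peak of Hml overlapped no relaxed peak of replicate 3. Germline genes had 6 of 18 against 33.9% (adjusted exact p = 1), with bgcn at 951.8, orb with Cdc16 at 530.3, zpg with Rexo5 at 283.4 and stau with Spn55B at 264.8, and without AGO3, aub, bam and krimp. The peak of stau overlapped no relaxed peak of replicate 2. Heat shock genes had 6 of 16 against 31.2% (adjusted exact p = 0.75), with Hsp83 with CG14965 at 1414, Hsp27 at 920.9, Hsp26 at 555.2 and Hsc70-4 with tefu at 540.5, and without Hsp22, Hsp23, Hsp67Ba and Hsp67Bc. Of 290 tRNA genes 37 were occupied, 12.8% against 16.4% (adjusted exact p = 0.18), and the direction of this list depended on the setting. It was below expectation with promoters of 500 bp (ratio 0.442, adjusted exact p = 4.0e-04), without strata (0.593), without transposable elements in the background (0.583) and in replicate 2 alone (0.662). With strata of gene length it was above expectation (1.55, adjusted exact p = 0.030). With summits in the gene body counted it was also above (1.48), but that setting used strata of gene length too. It held 38 occupied genes, while the expected share fell to 8.86%. The adjusted p over the alternatives ranged from 4.0e-04 to 0.80.

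**Figure D2:**
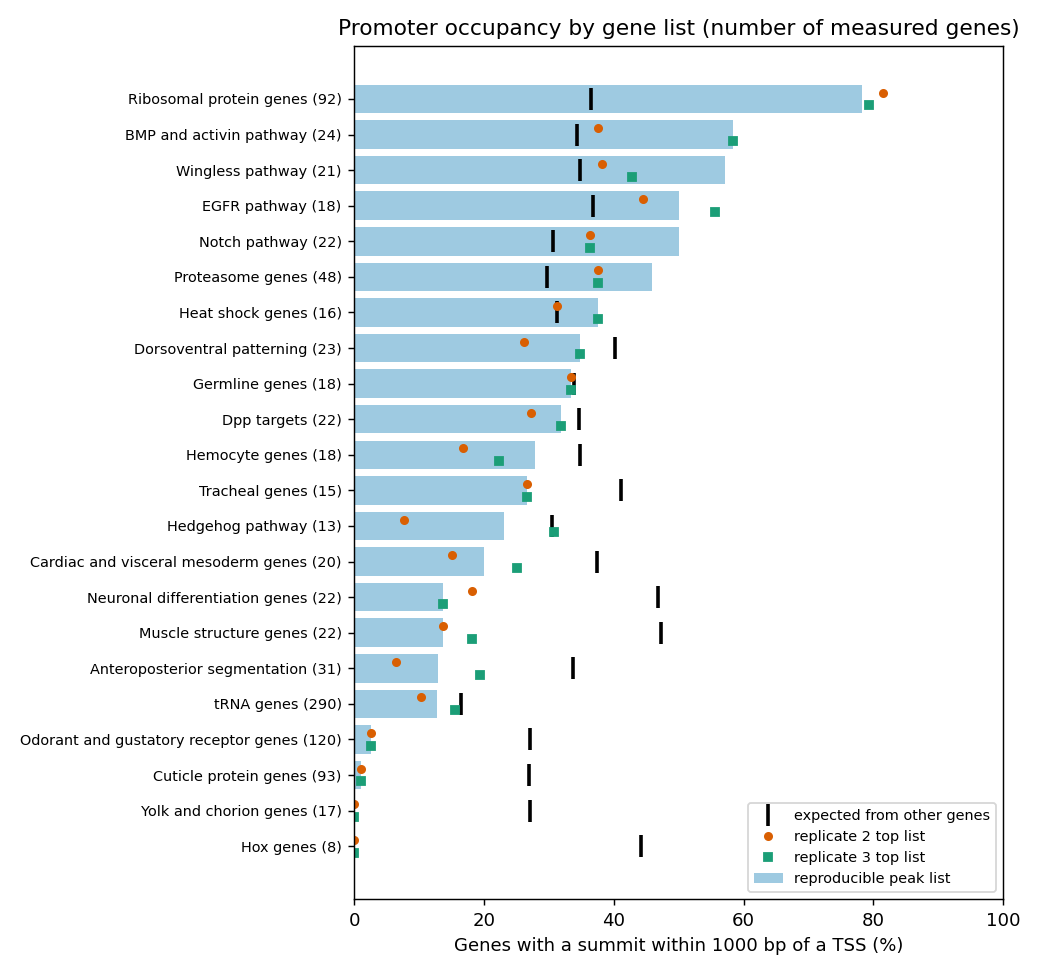
Share of measured genes of each fixed list with a summit within 1000 bp of a TSS, in percent, as bars for the reproducible list, circles and squares for the top lists of replicates 2 and 3, and vertical marks for the share expected from other genes with as many TSSs. Ribosomal protein genes reach 78.3% against 36.5% expected, and cuticle protein genes stay at 1.08% against 26.9%.

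Sites of the promoter factors DREF and M1BP had the highest ratios among the fixed motifs that passed, and the GC-rich sites of Mad were rarer at summits than beside them. The DREF site TATCGATA was found in 3.36% of the windows that reach 50 bp to each side of reproducible summits (Wilson 95% interval 2.93 to 3.85) and in 0.366% of windows 500 bp away (ratio 9.16, exact sign test, adjusted p = 1.0e-35), with ratios of 9.37 in replicate 2 and 7.06 in replicate 3. The M1BP site YGGTCACACTR was found in 1.16% against 0.068% (ratio 17, adjusted exact p = 1.1e-13), with 27.5 and 12.9 in the replicates. The DREF enrichment lay in promoter peaks, 193 of which held the site (ratio 10.7, adjusted exact p = 2.2e-35), while 4 distal peaks did (ratio 1.14, adjusted exact p = 0.49). The summit and flank windows with the site were divided differently at promoter (193 and 36) and distal peaks (4 and 7; two-sided Fisher exact test chosen after the data were seen, p = 7.1e-04).

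The Mad site GCCGNC was found in 8.23% of summit windows against 13.4% of flanks (ratio 0.616, exact sign test, adjusted p = 4.1e-21), with ratios of 0.408 in replicate 2 and 0.800 in replicate 3, and GNCGNC in 15.7% against 23.6% (ratio 0.667). Against dinucleotide-shuffled summit windows both were more frequent, at ratios of 1.16 and 1.101 (adjusted exact p = 0.035 for both), while GTCT was less frequent, at 0.807 (adjusted exact p = 1.2e-18). The Smad box GTCT was lower at summits, 32.0% against 35.3% (ratio 0.906, adjusted exact p = 1.3e-05), and in replicate 3 alone the ratio was 0.972 and missed the threshold (adjusted exact p = 0.17). The activating Mad-Med site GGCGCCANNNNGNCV occurred at 13 summits, 0.222% against a mean of 0.068% over both flanks (ratio 3.25). The flank drawn for the test held 0 sites (adjusted exact p = 5.7e-04), and 20 other draws gave larger adjusted p from 0.013 to 0.43, of which 8 passed. That call was lost in each replicate alone. The silencer site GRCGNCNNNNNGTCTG occurred at 3 summits and the palindrome GTCTAGAC at 7, neither past the threshold (adjusted exact p = 1 and 0.45). GC content averaged 38.9% in summit windows and 43.5% in flanks, with 36.4% and 44.0% in replicate 2 and 40.8% and 43.0% in replicate 3.

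Of the other motifs, TATAAA (ratio 1.38), the GATA site WGATAR (1.20) and the control hexamer TTGACA (1.24) were higher at summits by the same sign test, and GAGAGAG (0.658, with 0.399 in replicate 2 and 0.927 in replicate 3), CACACACA (0.438, with 0.268 and 0.704), the E-box CANNTG (0.928) and CACATG (0.809) were lower. In replicate 3 alone WGATAR, TTGACA, GAGAGAG, CANNTG and CACATG did not pass, and CACATG did not pass in replicate 2 either. Over 20 other draws of the flank TTGACA passed in 15 (adjusted exact p up to 0.089), CACATG in 15 (up to 0.18) and GAGAGAG in 19 (up to 0.062). Against shuffled windows, TATAAA was at 1.02 and WGATAR at 0.933, neither past the threshold, TTGACA turned to 0.917 without passing, and CANNTG (1.12, adjusted exact p = 6.1e-06), GAGAGAG and CACACACA (3 for both) turned to higher. The motifs of Brinker, Zelda, Tinman, Grainyhead, Pangolin and the initiator did not pass, with ratios between 0.893 and 1.16.

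**Figure D3:**
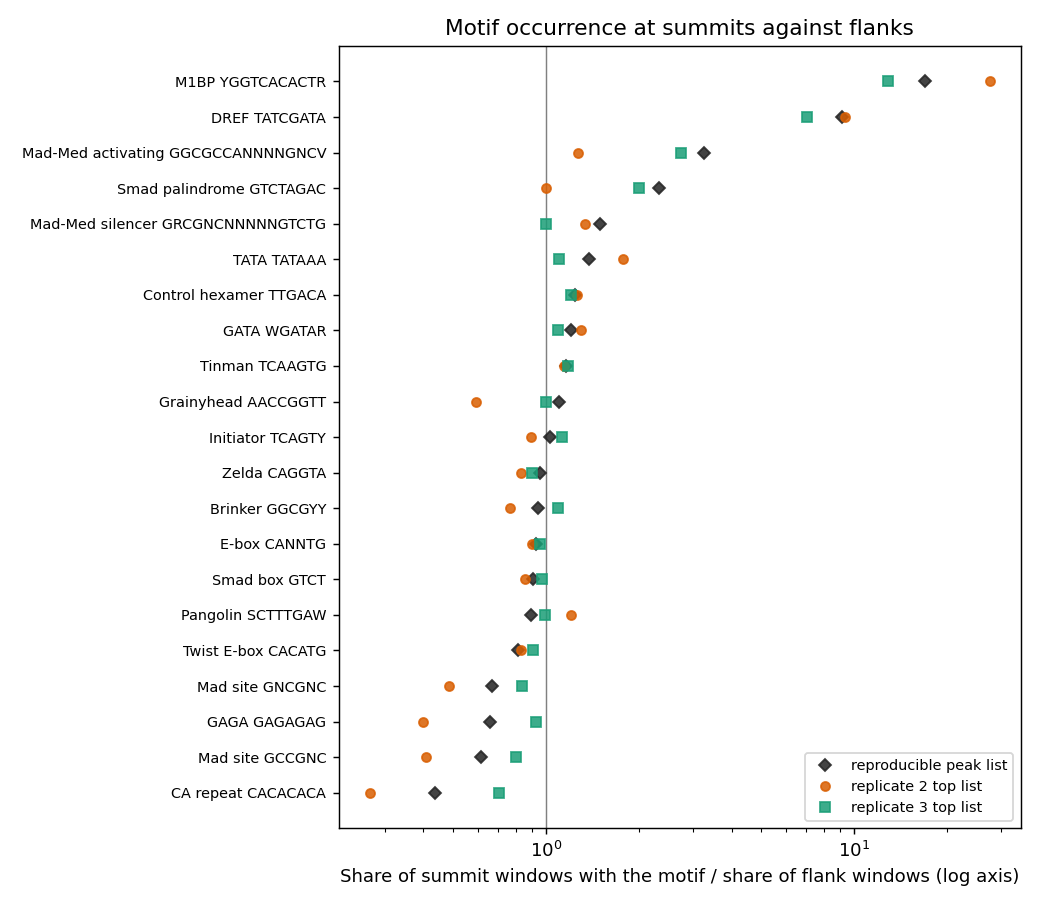
Ratio of the share of summit windows with each motif to the share of flank windows, on a log axis, for the reproducible list (diamonds) and the top lists of replicate 2 (circles) and replicate 3 (squares). DREF and M1BP sites lie farthest to the right at 9.16 and 17, and the Mad sites lie left of 1 in both replicates.

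In dm3 the reproducible list held 6408 peaks that covered 1.93 Mb, against 5867 peaks and 1.71 Mb in dm6, with a median width of 380 bp and signals from 150.2 to 8099.8. Of the dm3 list, 2 peaks lay outside the 6 arms, on 2RHet and 3RHet. The overlap of the replicates within 100 bp was 65.0% in dm3. Genes were not assigned to dm3 peaks, because no dm3 annotation was used here.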

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

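The tests of extra gene copies, of pull-down independent of Med and of DREF sites at promoter against distal peaks were chosen after the results were seen. The dm3 lists, which the gene comparisons did not use, hold peaks outside the 6 main arms: 221 in replicate 2 and 13 in replicate 3. In replicate 2 they lay mostly on 2RHet (92), 3LHet (63) and 3RHet (33), and the pooled list held 22 and the reproducible list 2.

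Relaxed peaks crowd the Med locus in replicate 3 and not in replicate 2. In the 25000 bp around Med, the pooled relaxed list held 25 peaks, more than in 99.9% of 1604 windows with a similar number of TSSs, and replicate 3 ranked at the 99.8 percentile of them, which argues against the promoter density of the locus for that replicate, while the 9 peaks of replicate 2 ranked at the 52.2 percentile, as promoter density alone would give. Extra copies of sequence around Med in the transgenic line are a candidate explanation. The density of peaks away from promoters ranked at the 99.9 percentile of windows in replicate 3, which goes with copies, and at the 62.6 percentile in replicate 2, which does not. Much of the crowding lay not in Med but upstream, inside CycG. There replicate 3 had peaks from 31600948 to 31608215, while the first peak of replicate 2 in the window was at 31608980. Copies would give these peaks only if the copied sequence reached that far, which is not known here. The replicates disagree, so copies stay open, as does a difference between the libraries, and no biological explanation was tested, because the design has 1 group.

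Mad sites GCCGNC are rarer at summits than in flanks, where GC content is higher. Base composition is a candidate explanation: against shuffled copies of the summit windows the ratio was 1.16 (bootstrap 95% interval 1.03 to 1.32). The interval crossed the bound of 1.1 set in advance. Flank windows were not shuffled, so this ratio cannot show whether the deficit against flanks persists once composition is accounted for. The explanation stays open. No biological explanation was tested.

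DREF and M1BP sites are more frequent at summits than in flanks. For DREF, base composition is argued against by a ratio of 17.9 for TATCGATA to shuffled windows (bootstrap 95% interval 10.4 to 39.6). No such ratio could be given for M1BP, whose site was in 1.16% of summit windows and 0% of shuffled windows. Equal enrichment of DREF sites at distal summits is argued against, because they held 4 windows with TATCGATA (ratio 1.14, interval 0 to 4) where the promoter ratio of 10.7 would give 37.5 (two-sided Fisher exact test of the difference, p = 7.1e-04), but whether distal summits have any enrichment, and so whether position at promoters is the whole cause, stays open. Position was not tested for M1BP, whose site was at 65 promoter and 3 distal summits, with a distal flank share of 0%. Pull-down of active promoters without Med may also contribute: tRNA genes, which it was assumed to raise, stood at 0.778 times the expected share (exact stratified test, adjusted p = 0.18). They were below it past the threshold at 500 bp (0.442), without strata (0.593), without transposable elements (0.583) and in replicate 2 alone (0.662). They were above it with strata of gene length (1.55). The count over the gene body (1.48) used the same strata, so it is not an independent setting. The settings disagree, and the assumption about tRNA genes was made without data on their transcription, so pull-down stays open. A control precipitation was not used here, and no biological explanation was tested.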

How the results depend on the processing

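The alternatives on peaks in both top lists, renamed symbols, transposable elements and other flank draws were chosen after the data were seen. Of the values under alternatives that could change them, 368 kept their direction and side of the threshold, moved by less than their spread or, for counts, stayed within 1.5 times, 59 lost a call, 15 gained one, 46 turned direction and 22 moved. Replicate overlap was 79.1% for the top 1000 peaks, 68.3% for the top 5000, 71.5% with any overlap of 1 bp, 57.3% at 50 bp, 71.4% at 250 bp and 65.0% in dm3. The signal correlation was 0.692 in the stricter list and 0.727 as Pearson r of log2 signal. Of the reproducible peaks 3955 had summits in both top lists. The difference between promoter and distal signal ranged from 12.98 to 27.8 without replicate 2 or replicate 3, on list scales whose sizes cannot be compared. The X ratio was 1.08 against arm length, and the ratio of CACACACA ranged from 0.268 to 0.704 without replicate 2 or replicate 3. The promoter share was 53.5% at 500 bp and 46.1% at 250 bp. Lists above expectation numbered 1 in the stricter list, 1 among peaks in both top lists, and 1 to 1 without replicate 2 or replicate 3. Lists below numbered 3 in the stricter list, 4 among peaks in both top lists and 4 without strata. Motifs above flanks numbered 2 at distal summits. Motifs below numbered 2 against shuffled windows, 4 against flanks at 2000 bp, 4 at promoter summits, and 3 to 7 without replicate 2 or replicate 3. The strongest pooled peaks are the reproducible list itself, so that alternative could change nothing and is not among these counts. M1BP had no value against shuffled windows or at distal summits, where the background share was 0. The values that follow are ratios to the expected or flank share, or to the share in shuffled summit windows where those are named. A direction that turned against shuffled windows comes with another comparator than the flanks. The cause was not tested for any of these values. At 5000 bp, calls ended for BMP and activin (1.14), Hox (0.806), Proteasome (1.26), and calls were gained for Wingless (1.48), Notch (1.59), and direction turned for Dpp targets (1.24), Hedgehog (1.04), Tracheal (1.00), Germline (1.33), tRNA (1.11). With summits in the gene counted and strata also of gene length, calls ended for BMP and activin (1.28), Hox (0.813), and direction turned for Dpp targets (1.29), Dorsoventral patterning (1.104), tRNA (1.48). Without strata, calls ended for Anteroposterior segmentation (0.412), Hox (0), Muscle (0.436), Neuronal (0.436), Proteasome (1.47), and calls were gained for tRNA (0.593), and direction turned for Dpp targets (1.02), Dorsoventral patterning (1.11), Germline (1.07). In the stricter list, calls ended for BMP and activin (1.40), Anteroposterior segmentation (0.318), Hox (0), Neuronal (0.311), Yolk and chorion (0), and direction turned for Wingless (0.675), Proteasome (0.944). Among peaks in both top lists, calls ended for Hox (0), Neuronal (0.379), Proteasome (1.30), Yolk and chorion (0), and direction turned for BMP and activin (0.958), Wingless (0.54), Notch (0.988), EGFR (0.989). At 500 bp, calls ended for BMP and activin (1.23), Anteroposterior segmentation (0.43), and calls were gained for Wingless (1.84), tRNA (0.442), and direction turned for Germline (1.102). With length strata, calls ended for BMP and activin (1.51), Yolk and chorion (0), and calls were gained for Notch (1.79), and direction turned for tRNA (1.55). Without list genes in the background, calls ended for Proteasome (1.53). Without transposable elements, calls were gained for tRNA (0.583). Without replicate 2 or replicate 3, ratios whose call or direction changed ranged as BMP and activin 1.15 to 1.67, Anteroposterior segmentation 0.201 to 0.565, Germline 0.966 to 1.03, Proteasome 1.24 to 1.32, tRNA 0.662 to 0.932. Against shuffled windows, calls ended for Mad-Med activating (3.25), Twist E-box (0.845), TATA (1.02), and calls were gained for Zelda (0.636), Tinman (1.43), Initiator (1.15), and direction turned for Mad GCCGNC (1.16), Mad GNCGNC (1.101), Brinker (1.24), GAGA (3), GATA (0.933), E-box (1.12), CA repeat (3), Control hexamer (0.917). At promoter summits, calls ended for Smad box (0.936), Mad-Med activating (1.67), GATA (1.09), E-box (0.95), Twist E-box (0.867), and direction turned for Mad-Med silencer (0.667). In the stricter list, calls ended for Mad-Med activating (1), E-box (0.947), and calls were gained for Brinker (0.871), and direction turned for Smad palindrome (0), Pangolin (1.14), Initiator (0.922). In narrower windows, direction turned for Mad-Med silencer (0), Pangolin (1.03). In wider windows, calls ended for GAGA (0.836), E-box (0.973), and direction turned for Mad-Med silencer (0.909), Grainyhead (0.75). Among peaks in both top lists, calls ended for Mad-Med activating (2.80), and calls were gained for Brinker (0.879), and direction turned for Pangolin (1.11), Initiator (0.938). At distal summits, calls ended for Mad-Med activating (8), GAGA (0.618), DREF (1.14), Twist E-box (0.726), Control hexamer (1.18), and direction turned for Zelda (1.20), Grainyhead (0.857), Initiator (0.917). Against flanks at 2000 bp, calls ended for GAGA (0.975), Twist E-box (0.888), CA repeat (0.809), and direction turned for Tinman (0.8996). Without replicate 2 or replicate 3, ratios whose call or direction changed ranged as Smad box 0.852 to 0.972, Mad-Med activating 1.27 to 2.75, Brinker 0.762 to 1.096, GAGA 0.399 to 0.927, GATA 1.09 to 1.30, Grainyhead 0.593 to 1, Pangolin 0.994 to 1.20, E-box 0.901 to 0.957, Twist E-box 0.83 to 0.905, Initiator 0.894 to 1.12, Control hexamer 1.20 to 1.26.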

Other observations

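The sets described and the test on words were chosen after the data were seen. Of 5334 reproducible peaks with a summit of both relaxed lists within 100 bp, 156 had at least 4 times more signal in replicate 3 than in replicate 2 relative to the median ratio, and 6 the opposite. The 156 peaks had a mean GC content of 47.7% against 38.5% over all matched peaks, held the Mad site GCCGNC in 16.0% of windows against 8.33% of their flanks, and over all matched peaks these shares were 8.02% and 13.4%. They held GAGAGAG in 6.41% of windows against 1.44% over all matched peaks, TATCGATA in 0.641% against 3.45% and TATAAA in 8.33% against 15.2%. Among peaks found in both lists the largest ratios were at emc, the gene of an HLH repressor (22.8 in replicate 2 and 349.3 in replicate 3), l(2)k01209 (22.6 and 339.4), and a peak 5504 bp from a TSS of InR, the insulin receptor gene (23.7 and 344.5). These replicate 2 values lie close to 21.4, the lowest of its list, below which no ratio could be given, so the order of these peaks depends on where that list ends. Promoter peaks of dorsoventral patterning genes had a median log2 ratio of 1.78 over 11 peaks relative to all peaks, 5 of them at least 4-fold to replicate 3, and proteasome genes of -0.06 over 21. Ribosomal protein genes had 0.62 over 76 peaks. No test was made of these differences.

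Words of 8 bases were ranked on the 2175 peaks of arms 2L and 2R among 474 words found in at least 30 windows, and the first 8 were counted on the other 3692 peaks. TATCGATA was in 3.60% of those windows against 0.366% of flanks, CAACACTG in 2.44% against 0.339%, GGTCACAC in 1.87% against 0.176% and CAGCCCTG in 1.25% against 0.135%. All 8 were higher at summits on the held-out arms (exact sign test, largest adjusted p = 4.0e-08). CAACACTG and CAGCCCTG were not among the fixed motifs.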
